A study of Drosophila melanogaster with 15 samples.

How the data were processed

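RNA came from dissected muscle of adult male flies grown at 27 °C. According to the labels, thoraces of 30 wild-type or 60 salm RNAi males were dissected for IFM and 360 legs for leg muscle, and 500 ng of total RNA was amplified and labelled. Each array held a sample and a reference pooled from the samples, and wild-type flies carried the driver Mef2-GAL4 alone. The series described biological duplicates plus 1 technical array, in which a labelled sample was hybridised to a further array. This gave 10 biological samples on 15 arrays, 9 in the Cy5 set (wild-type IFM replicates 1 and 2, TF3029, TF10152) and 6 in the Cy3 set (wild-type IFM replicates 3 and 4, leg muscle). Nothing in the labels beyond the word biological says how the duplicates were raised or dissected, and p-values measure only the spread between these samples, which may be technical.

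The scanner files hold, per the file headers, the median pixel intensity of each spot and of its local background in both channels, and processed signal intensities that the scanner software had background-subtracted and dye-normalised within the array. They also hold the log10 ratio of processed red over green signal, made by the same software per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1, while the file headers give 10.5.1.1 for the Cy5 set and 10.7.3.1 for the Cy3 set. The study's value table agrees within rounding with the log10 ratio of the files for 100% of spots in the Cy5 set and with its negative in the Cy3 set, so that it reads sample over reference with the dyes as labelled. Its column medians ran from -0.0802 to 0, and its centring is not stated. No mean foreground signal was used: the plan assumed means, and the files gave medians.

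Direction was settled from the intensities before any gene's change was seen, and it departs from the plan, which took it from the labels. The sample channel was taken as green in the Cy5 set and red in the Cy3 set, because that channel differed the more between groups. Spots whose group means lay 2-fold apart numbered 495 in red and 4803 in green in the Cy5 set, and 3528 in red and 108 in green in the Cy3 set. The labels and the study's table run the other way, and the dyes as labelled were run as an alternative.

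Medians were corrected with normexp (offset 50) on all spots and normalised within each array by loess with control spots at weight 0. The 1417 control spots and spots flagged as outliers were then left out. Spots of a probe were averaged, as were the arrays of a biological sample. A probe was kept if it was well above background in the sample channel on every array of at least 1 group, with the probe counted on an array when 0.5 or more of its spots were. A gene or identifier was represented by its kept probe with the highest mean intensity, and where probes of a gene disagreed the table holds both ends. CG1674 had leg changes of -2.18 and 0.93 from its 2 probes and is not used in the report, the probes of how ran from 1.80 to 2.17 in leg muscle, and those of Rab26 stood at 0.23 and 0.64 in salm RNAi IFM. Of 32162 probes, 256 matched 1 gene, 0 matched several and 31906 were unnamed here, through the gene table of assembly Release 6 plus ISO1 MT, of which no coordinates were used. Most identifiers, 20647 probes, are transcript identifiers that the table does not hold, and the files do not pair them with symbols. The name of 1029 probes differed between the array designs of the sets. A list of 230 genes was named, and 163 of them were tested.

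Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 5 group means over 10 samples, residual df 5, prior df 2.78), with Benjamini-Hochberg adjustment over the 16547 transcripts tested and a threshold of 0.05. Leg muscle was set against wild-type IFM replicates 3 and 4, and salm RNAi IFM (the mean of both lines) and each line against replicates 1 and 2, so that every change lies within a dye set. The difference between the salm RNAi change and the leg change was a contrast of the same model. It spans both dye sets and holds only if dye and set effects are additive. A change is reported as log2 with its standard error, or as a fold. Where a gene was not well above background on any array of a group, the fold is a bound: the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the gene's own signal, per channel after loess and Aquantile, which leaves it open to dye bias. The bound carries no sampling error, so for a change that did not pass it is no lower limit. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 drew the figures.

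The groups, the tests, the alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. The rule named, for leg muscle and for salm RNAi IFM, salm and salr and the 8 largest rises and 8 largest falls past the threshold whose replicates all lay on the same side of wild type, bare CG or CR numbers left out. It added up to 4 members of each list described, the 4 largest in each direction between the lines and between the changes, and the 4 largest shared rises and falls. Lists were tested with camera (preset correlation 0.01, and an estimated one) if 3 or more members were tested. Of the 30 lists 1 reached that, oxidative phosphorylation. Lists with 1 or 2 tested members were muscle identity regulators and splicing regulators (how in both), attachment proteins (LanA), mitochondrial ribosome and import (Tim10), heat shock and stress (Sod1), cytosolic ribosome (RpL7 and sta) and sex markers (roX1 and roX2), with their values in the report. No member was tested of the other lists, among them fibrillar and tubular isoforms, sarcomere proteins, calcium handling, glycolysis, neurons, glia, fat body and cuticle. After the names on the array were known, and before any value was seen, 7 lists were added, of which mitochondrial proteins, ribosomal proteins and neuronal and sensory genes were tested. In the smaller added lists Acp53C14a stood at 0.90 in leg muscle and -0.85 in salm RNAi IFM, and Acp95EF at -0.26 and 0.26. Acp65Aa stood at 0.53 in leg muscle. In salm RNAi IFM, with no wild-type array well above background, Acp65Aa stood above wild type by a bound of 1.68-fold. None of these changes passed. Cyp4g1, of the list of cuticle and oenocyte genes, is given in the report. The immune gene PGRP-LA rose in both comparisons (0.50 and 0.54, limma adjusted p 0.0202 and 0.00941), and of the lines it passed in TF3029 (0.84) and not in TF10152 (0.25, adjusted p = 0.258).

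The fit was tested on simulated data with 200 changed transcripts among 16547. For leg muscle it recovered 71% of changes of log2 1 and 95% of changes of log2 2, and called 10 of 16347 unchanged transcripts. For salm RNAi IFM the shares were 84% and 99%, again with 10 calls among the unchanged. The simulated errors were independent between samples, had the model's own spread and held no scan day, slide or dye effect. The 10 calls are thus no false-call rate for the real comparisons. Alternatives covered background, normalisation, filters, probes, technical arrays, dye set, replicate block, scan day and slide, thresholds and each sample left out; some were added after the data were seen, and the closing section names them. The arrays fell on 4 scan days and 5 slides by their codes, and 4 arrays carried a barcode found on another array. Each such barcode joined a wild-type IFM array of the Cy5 set to an array of TF3029 replicate 1. The doubt about which array is which thus falls on the TF3029 and salm RNAi comparisons. No comparison had 3 or more samples in each group, so other splits of the samples were not counted.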

Results

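Gene expression was measured in muscle of adult male Drosophila melanogaster. Indirect flight muscle (IFM) is the fibrillar muscle that powers the wing beat, and leg muscle is tubular. The study set wild-type IFM beside leg muscle and beside IFM in which salm, the gene for the zinc finger transcription factor Spalt major, was targeted by RNA interference under Mef2-GAL4, a driver active in muscle. The labels gave 4 groups: wild-type IFM (4 biological samples), wild-type leg muscle (2), IFM with the salm hairpin TF3029 (2) and IFM with the salm hairpin TF10152 (2). Every sample was hybridised with a pooled reference on an Agilent array with 2 dyes. Wild-type IFM replicates 1 and 2 and both hairpin lines carried Cy5 according to the labels, and wild-type IFM replicates 3 and 4 and leg muscle carried Cy3. With 5 further arrays named as technical replicates there were 15 arrays. Of 43603 probe spots per array, 26744 to 39527 were well above background in red and 18741 to 38797 in green, and the number of arrays limited the precision. The test covered 16547 transcripts or array identifiers, of which 163 could be given a gene name here, so genes are named from those 163 while counts cover all of them. The genes salm and salr were not among the named ones, and the knockdown itself was not checked here.

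The direction of every change below rests on a reading of the dyes that opposes the labels and the study's own table of values, which went with the labels. In both dye sets the channel labelled as the sample was nearly alike in all groups, while the channel labelled as the reference differed between groups. Over 16615 spots well above background and not saturated on all arrays, in the Cy5 set the mean Spearman correlation between arrays of different groups was 0.931 in the labelled sample channel and 0.829 in the labelled reference channel. In the Cy3 set the same means were 0.982 and 0.829. A common reference is the same material on every array, so the channel that differed between groups was taken as the sample. With the dyes as labelled the sign of every change turns, and the numbers of changed transcripts under that reading are given with the counts below.

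**Figure D1:**
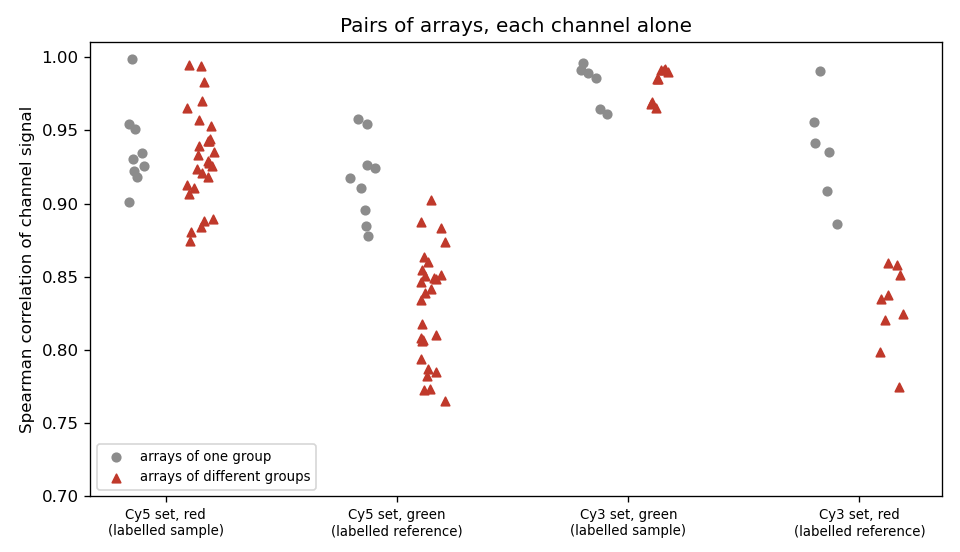
Each point is the Spearman correlation (vertical axis, no unit) of median spot signal, not background-corrected, between 2 arrays in a single channel, for pairs from 1 group (grey circles) and pairs from different groups (red triangles). In the channels labelled as the reference, pairs from different groups averaged 0.829 in each set, below the pairs from 1 group, which averaged 0.917 in the Cy5 set and 0.936 in the Cy3 set.

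Leg muscle was compared with wild-type IFM to find the transcripts that differ between dissected tubular muscle and the fibrillar flight muscle. Cells other than muscle may differ between the dissections as well, and cell composition was not measured. Transcripts of flap were 17.3-fold higher in leg muscle (log2 change 4.11 ± 0.23, SE, n = 2 and 2). CLIP-190, a microtubule plus-end binding protein, was 5.55-fold higher (2.47 ± 0.16), and how, which encodes the RNA-binding protein Held out wings, was 4.51-fold higher (2.17 ± 0.17). ATPsynbeta, the catalytic subunit of ATP synthase, was 3.70-fold lower in leg muscle (-1.89 ± 0.12). Other named transcripts that rose were Cyp4g1, a cytochrome P450 of hydrocarbon synthesis in oenocytes (2.19 ± 0.36), and Snmp1, a membrane protein of sensory neurons (1.84 ± 0.15). Mbs, the myosin-binding subunit of myosin phosphatase, rose by 1.64 ± 0.20, the serpin gene Spn77Ba by 1.60 ± 0.13 and the small RNA sncRNA:158 by 1.69 ± 0.25. The largest named fall was that of the noncoding RNA lncRNA:alphagamma-element:CR32865 (-2.61 ± 0.36), followed after ATPsynbeta by lncRNA:sphinx (-1.68 ± 0.25) and snoRNA:U3:9B (-1.36 ± 0.44). COX5BL, related to a subunit of cytochrome c oxidase, changed by -1.33 ± 0.18, the complex I subunit ND-B14.7 by -1.26 ± 0.30, and the mitochondrial ribosomal protein genes mRpL52 and mRpS33 by -1.26 ± 0.24 and -1.22 ± 0.16. Adjusted p from limma with Benjamini-Hochberg adjustment was 1.63e-05 for flap, 2.70e-05 for ATPsynbeta, 6.31e-05 for how and 0.0420 for snoRNA:U3:9B. Both leg replicates lay on the same side of both wild-type replicates for each of these genes, which the rule that named them required. Of unnamed identifiers, FBtr0082786 rose by 5.65 ± 0.16 and FBtr0086075 changed by -4.80 ± 0.29. The median change of all transcripts was -0.12, and relative to it flap rose by 4.23 and ATPsynbeta changed by -1.77.

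Among the 16547 transcripts, 2467 were higher and 3930 lower in leg muscle at an adjusted p under 0.05 (limma, two-sided), of which 1246 and 1507 changed at least 2-fold. With the dyes as labelled, 4720 were higher and 2476 lower. With median centring in place of loess the median of all transcripts moved to 0.29, 5692 were higher and 1441 lower, and the share higher went from 38.6% to 79.8%; the calls of COX5BL, ND-B14.7, mRpL52, mRpS33 and snoRNA:U3:9B ended, and those of flap, CLIP-190, how, Mbs, Spn77Ba and ATPsynbeta held under all alternatives run on them. With the slide as a block 1487 were higher and 1364 lower, and on the slide that held all leg arrays and 1 wild-type array 1778 and 2764, where the lone wild-type sample added no spread of its own. The 2 leg replicates correlated at 0.998, above the 0.903 between replicate 1 and its own technical array, so the p-values of this comparison can rest on technical spread alone; with each group of the Cy3 set counted as 1 sample, 1306 were higher and 1188 lower. The count of lower transcripts was 2280 without wild-type IFM replicate 3, 2369 without leg replicate 1 and 2287 without leg replicate 2. The call of snoRNA:U3:9B was lost in 18 of the 31 settings run on it, and that of ND-B14.7 in 7, among them wild-type IFM replicate 3 left out (-1.15, limma adjusted p = 0.0720), leg replicate 2 left out (-1.18, adjusted p = 0.0663) and the slide as a block (-1.09, adjusted p = 0.0862). With each Cy3 group as 1 sample ND-B14.7 (-1.27, limma adjusted p = 0.149), mRpL52 (-1.27, adjusted p = 0.0935), lncRNA:sphinx (-1.61, adjusted p = 0.0528) and Cyp4g1 (2.19, adjusted p = 0.0713) did not pass. The sample channel alone ended the calls of lncRNA:sphinx (-0.55, limma adjusted p = 0.601) and Cyp4g1 (2.11), the slide as a block that of sncRNA:158 (1.24, adjusted p = 0.166), and the fit without a dye set term those of lncRNA:alphagamma-element:CR32865 (-1.45, adjusted p = 0.206) and Snmp1 (1.23, adjusted p = 0.0575). Regrouping the arrays by correlation ended those of sncRNA:158, Cyp4g1 and lncRNA:alphagamma-element:CR32865 (limma adjusted p 0.0587, 0.0525 and 0.0807).

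IFM with salm RNAi was compared with wild-type IFM to find the transcripts that change when salm is targeted in flight muscle. Wild-type flies carried the driver and no hairpin. Effects of expressing any hairpin therefore cannot be told from those of losing salm. COX5A, a subunit of cytochrome c oxidase, was 6.08-fold lower (-2.60 ± 0.31, SE, n = 4 samples of 2 lines and 2 wild-type samples). ND-23, an iron-sulphur subunit of complex I, was 6.07-fold lower (-2.60 ± 0.17), and ND-B14.7, another complex I subunit, was 5.33-fold lower (-2.42 ± 0.26). Each line had its own mean in the model. The standard errors and p-values of this comparison therefore hold the spread within lines and not that between the 2 lines. The polarity gene scrib was 2.10-fold higher (1.07 ± 0.13) and LanA, a laminin chain of the basement membrane, was 2.00-fold higher (1.00 ± 0.12). Further falls were those of lncRNA:sphinx (-2.53 ± 0.21), mRpL52 (-1.98 ± 0.21), ATPsynbeta (-1.72 ± 0.10), COX5BL (-1.63 ± 0.15) and Sdhaf3, an assembly factor of succinate dehydrogenase (-1.34 ± 0.15). Further rises were those of sncRNA:158 (1.09 ± 0.22), 7SLRNA:CR32864, the RNA of the signal recognition particle (0.95 ± 0.19), and Uba1, the ubiquitin-activating enzyme (0.93 ± 0.12). Mbs rose by 0.90 ± 0.17, alpha-Spec, the alpha chain of spectrin, by 0.77 ± 0.12 and the small GTPase gene Rab26 by 0.64 ± 0.14. Adjusted p from limma with Benjamini-Hochberg adjustment was 3.40e-05 for ATPsynbeta, 4.96e-05 for ND-23, 0.000597 for COX5A, 0.000675 for scrib and 0.0109 for Rab26. All 4 salm RNAi replicates lay on the same side of both wild-type replicates for each of these genes, again as the naming rule required. By line, scrib passed in TF3029 (1.85) and not in TF10152 (0.29, limma adjusted p = 0.249), and Rab26 passed in TF10152 (1.11) and not in TF3029 (0.17, adjusted p = 0.443). Cyp4g1 fell by 1.25 on the log2 scale (SE 0.31, limma adjusted p = 0.0179), but the call was lost in 14 of 31 settings, among them the technical arrays left out (-0.40, adjusted p = 0.434), and the sign turned without the 4 arrays that share a barcode (0.48), where 1 wild-type and 1 TF3029 sample were left in the Cy5 set; by line it passed in TF3029 (-2.08) and not in TF10152 (-0.42, adjusted p = 0.519). Among unnamed identifiers, GH11417 rose by 3.98 ± 0.66 and IP05750 changed by -5.64 ± 0.25.

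At an adjusted p under 0.05 (limma, two-sided), 2353 transcripts were higher and 2998 lower in salm RNAi IFM, of which 676 and 1113 changed at least 2-fold. These counts were 3302 and 2319 with the dyes as labelled. With median centring 5180 were higher, which was 59.7% of the changed transcripts, and with the scanner software's processed signals 62.7% were higher and 1939 were lower; median centring ended the calls of Cyp4g1, Rab26 and Sdhaf3, and the calls of ATPsynbeta, COX5A, ND-23, ND-B14.7, mRpL52, lncRNA:sphinx, LanA and scrib held under all alternatives run on them. With the scan day as a block 557 were higher and 886 lower, and 1440 of 5229 calls held; no scan day held both TF3029 and wild-type IFM, and on scan day 1, which held TF10152 and wild-type IFM, 860 transcripts changed. Without wild-type IFM replicate 1 the counts were 1273 higher and 1598 lower, and without wild-type IFM replicate 2 they were 1099 and 1346. The technical array of wild-type IFM replicate 1 correlated at 0.867 with replicate 1 and at 0.962 with replicate 2, and that of TF10152 replicate 1 at 0.929 with replicate 1 and 0.974 with replicate 2, while that of TF3029 replicate 1 correlated at 0.968 with replicate 1 and 0.898 with replicate 2. With arrays regrouped by correlation within their group and dye set 976 were higher and 1351 lower. The call of Rab26 was lost in 9 of the 30 settings run on it, among them either wild-type replicate of the Cy5 set left out (0.67 and 0.61, limma adjusted p 0.0631 and 0.0876). The calls of 7SLRNA:CR32864, sncRNA:158 and Mbs were each lost in 5 of 31 settings. Without wild-type IFM replicate 2 these 3 stood at 0.64, 1.03 and 0.92 (limma adjusted p 0.0646, 0.0697 and 0.0511), and Mbs stood at 0.88 without replicate 1 (adjusted p = 0.0514). The scan day as a block ended the calls of 7SLRNA:CR32864, sncRNA:158, Mbs, alpha-Spec, Uba1 and Rab26 (limma adjusted p 0.206, 0.325, 0.0634, 0.0658, 0.0634 and 0.142), and regrouped arrays those of the first 3 and of Rab26 (adjusted p 0.128, 0.168, 0.0830 and 0.0639). Without a dye set term COX5BL did not pass (-0.80, limma adjusted p = 0.217).

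The genes of mitochondrial proteins were then taken as lists. Of the fixed list of oxidative phosphorylation genes, 3 of 50 were tested, ND-23, COX5A and ATPsynbeta. All 3 fell in leg muscle (median log2 change -1.12; camera adjusted p = 0.0202, adjusted p = 0.0804 with an estimated correlation) and all 3 fell in salm RNAi IFM (median -2.60; adjusted p = 0.000407, adjusted p = 0.0208 with an estimated correlation). The same counts, 3 and 3, came out adjusted over the list alone. With the slide as a block 1 of the 3 fell in leg muscle (median -0.90), and on the slide with all leg arrays 2 fell (median -0.93). A wider list of mitochondrial protein genes was written after the names on the array were known and before any value was seen, and it includes those 3. Of its 12 tested members 8 fell in leg muscle and none rose (median -1.03; camera adjusted p = 0.00792, adjusted p = 0.310 with an estimated correlation). In salm RNAi IFM 10 of the 12 fell (median -1.49; camera adjusted p = 8.32e-07, adjusted p = 0.0576 with an estimated correlation). The mitochondrial ribosomal protein gene mRpL40 changed by -0.47 in leg muscle and -1.16 in salm RNAi IFM, with limma adjusted p of 0.0305 and 0.000359. Beside these lists stand genes of other cell types: Cyp4g1, of oenocytes, rose in leg muscle (2.19) and fell in salm RNAi IFM (-1.25, within the limits above), and Snmp1, of sensory neurons, rose in leg muscle (1.84). Tim10 and Tim17a2, of the import machinery, passed in neither comparison (leg -0.39 and -0.38, salm RNAi -0.08 and -0.36). With the slide or scan day as a block 4 of the 12 fell in leg muscle (median -0.78) and 8 in salm RNAi IFM (median -1.39). On the slide with all leg arrays 6 fell (median -0.82), and on scan day 1 6 fell in TF10152 (median -1.23). The fall of COX5A in leg muscle (-1.12 ± 0.35, limma adjusted p = 0.0386) did not hold when either leg replicate or either wild-type replicate of the Cy3 set was left out (-1.17, -1.07, -1.01 and -1.22, adjusted p 0.0950 to 0.156). The fall of ND-23 in leg muscle (-0.95, limma adjusted p = 0.00754) did not hold without wild-type IFM replicate 3 (-0.77, adjusted p = 0.0533), without leg replicate 2 (-0.85, adjusted p = 0.0502), with median centring (-0.69, adjusted p = 0.0995), with the slide as a block (-0.66, adjusted p = 0.210) or with each Cy3 group as 1 sample (-0.98, adjusted p = 0.0764).

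**Figure D2:**
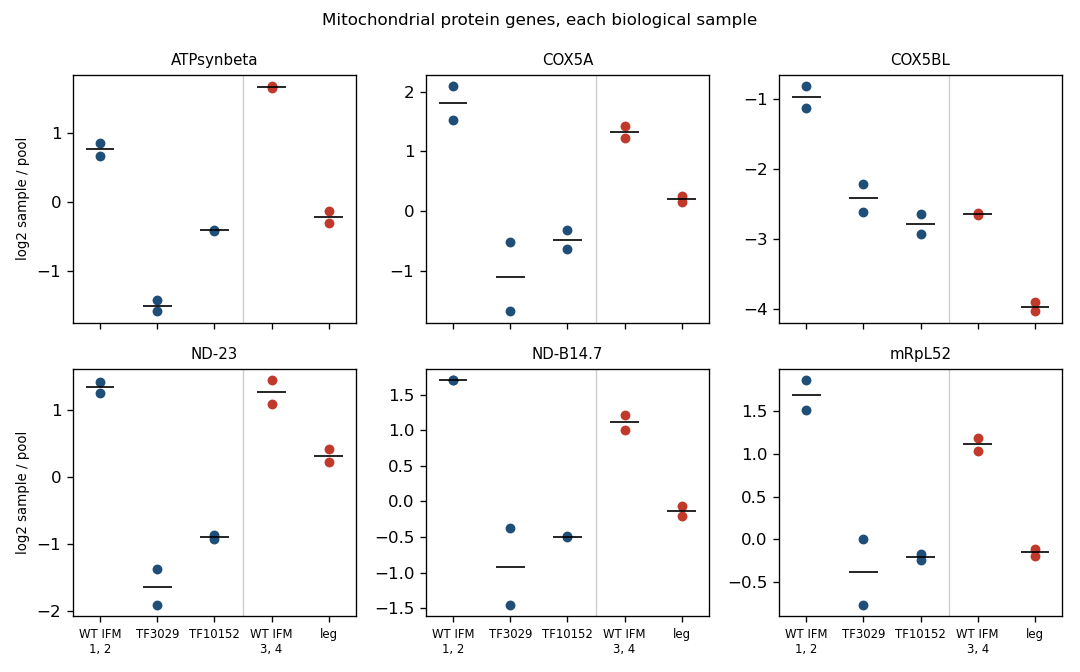
Each point is the log2 ratio of sample over pool for 1 biological sample, the horizontal line is the mean of a group, blue marks the Cy5 set and red the Cy3 set, with a vertical scale for each gene. The 6 genes drawn are members of the mitochondrial list that passed as lower in both comparisons, so their common direction follows from that choice. All 6 lay lower in both hairpin lines than in wild-type IFM replicates 1 and 2 and lower in leg muscle than in replicates 3 and 4. ATPsynbeta changed by -1.72 in salm RNAi IFM and -1.89 in leg muscle. Of the tested members not drawn, mRpL40 and mRpS33 also passed as lower in both, and ND-24L, Tim10, Tim17a2 and Sdhaf3 did not.

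Of 3 ribosomal protein genes tested, sta rose in leg muscle (0.55, limma adjusted p = 0.0255), and RpL7 and RpL29 did not pass (0.14 and -0.18). The call of sta was lost in 14 of the 31 settings run on it, among them either leg replicate or either wild-type replicate of the Cy3 set left out. None of the 3 passed in salm RNAi IFM. There RpL7, not well above background on any wild-type array of that set, was higher by a bound of 1.19-fold, which carries no sampling error. RpL7 did not pass (limma adjusted p = 0.0652), passed in 8 of 30 settings and stood at 0.04 on the log2 scale in its lowest setting. The camera adjusted p of that list was 0.598 for leg muscle and 0.489 for salm RNAi IFM. Of 5 neuronal and sensory genes, Snmp1 rose in leg muscle while brv3, a channel gene of cold sensing, and SK, a calcium-activated potassium channel gene, fell (-0.64 and -0.62). In salm RNAi IFM Rab26 rose and brv3 fell (-0.50; by line -0.91 in TF3029 and -0.09 in TF10152, where it did not pass), and the camera adjusted p of this list was 0.990 and 0.489. Median centring turned the sign of SK in leg muscle (0.17), and its call was lost in 19 further settings of 31, with limma adjusted p = 0.213 without wild-type IFM replicate 4 and 0.240 without leg replicate 1. The call of brv3 was lost in 10 of 30 settings in leg muscle and 11 of 30 in salm RNAi IFM. LanA, the 1 tested member of the list of attachment proteins, rose in both comparisons (0.60 in leg muscle, limma adjusted p = 0.0132). Its call in leg muscle was lost in 8 of 31 settings, among them wild-type IFM replicate 4 left out (0.47, limma adjusted p = 0.0794), leg replicate 1 left out (0.44, adjusted p = 0.0818), the slide as a block (0.65, adjusted p = 0.140) and each Cy3 group as 1 sample (0.61, adjusted p = 0.0553). The X-chromosome dosage compensation RNAs roX1 and roX2 did not pass in leg muscle (-0.09 and -0.40) or in salm RNAi IFM (-0.10 and -0.44). Sod1, a superoxide dismutase, rose in leg muscle (0.36, limma adjusted p = 0.0484) and did not pass in salm RNAi IFM (-0.21).

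The change from wild-type to salm RNAi IFM was set against the change from wild-type IFM to leg muscle, to see how far both went the same way. Cyp4g1, of oenocytes, and Snmp1, of sensory neurons, rose in leg muscle. The leg change may therefore hold cell composition as well as muscle type, and these were not separated. A gene that rose in leg muscle alone thus gives no measure of how far the muscle type moved. ATPsynbeta, lncRNA:sphinx, COX5BL and mRpL52 fell in both, and sncRNA:158, Mbs, alpha-Spec and LanA rose in both, within the limits given for single settings; with the sample channel alone alpha-Spec did not pass in leg muscle (0.63, limma adjusted p = 0.111). In contrast, flap rose in leg muscle and stood at -0.51 ± 0.20 in salm RNAi IFM, which did not pass (limma adjusted p = 0.0909) but did in 4 of 31 settings, such as TF3029 replicate 2 left out (-0.71, adjusted p = 0.00101), and the changes differed by -4.62 ± 0.31 (adjusted p = 5.92e-05). The changes of CLIP-190 and how differed by -2.17 ± 0.21 and -2.15 ± 0.22. In salm RNAi IFM how stood at 0.02 and CLIP-190 at 0.30, which did not pass (limma adjusted p = 0.135), though CLIP-190 rose by 0.55 in TF3029 (adjusted p = 0.0261; 0.05 in TF10152) and passed over both lines in 4 of 30 settings, such as TF3029 replicate 1 left out (0.41, adjusted p = 0.0170). With median centring how passed as well (0.66, limma adjusted p = 0.0338). Cyp4g1 differed by -3.43 ± 0.47, within the limit on its salm RNAi value given above. The differences of lncRNA:alphagamma-element:CR32865 (3.35 ± 0.48), 7SLRNA:CR32864 (1.54 ± 0.29), scrib (1.49 ± 0.20) and SK (1.14 ± 0.28) went the other way. ND-23 and COX5A changed more in salm RNAi IFM than in leg muscle (differences -1.65 and -1.49, limma adjusted p 0.00284 and 0.0471), while ATPsynbeta did not differ beyond the replicate spread (0.17, adjusted p = 0.484). In all, the changes differed for 4817 transcripts (limma, adjusted p under 0.05), and for 4784 with the dyes as labelled. The count was 1749 with the scan day or slide as a block, and 7791 with all arrays and the sample as a random block. These differences span both dye sets and hold only if dye and set effects are additive, which was not tested.

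Of the 3930 transcripts lower in leg muscle, 1361 were also lower in salm RNAi IFM, where independent lists would share 712.0. Of the 2467 higher in leg muscle, 618 were also higher, against 350.8. Transcripts lower in leg muscle and higher in salm RNAi IFM numbered 476 against 558.8, and those that went the other way numbered 300 against 447.0. Across transcripts, which are not independent replicates, the Pearson correlation of both changes was 0.243, and the comparisons shared no array. With the dyes as labelled 619 fell and 1652 rose in both (r = 0.268), with median centring 683 and 3196 (r = 0.395), and with the slide or scan day as a block 267 and 131 (r = 0.193).

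**Figure D3:**
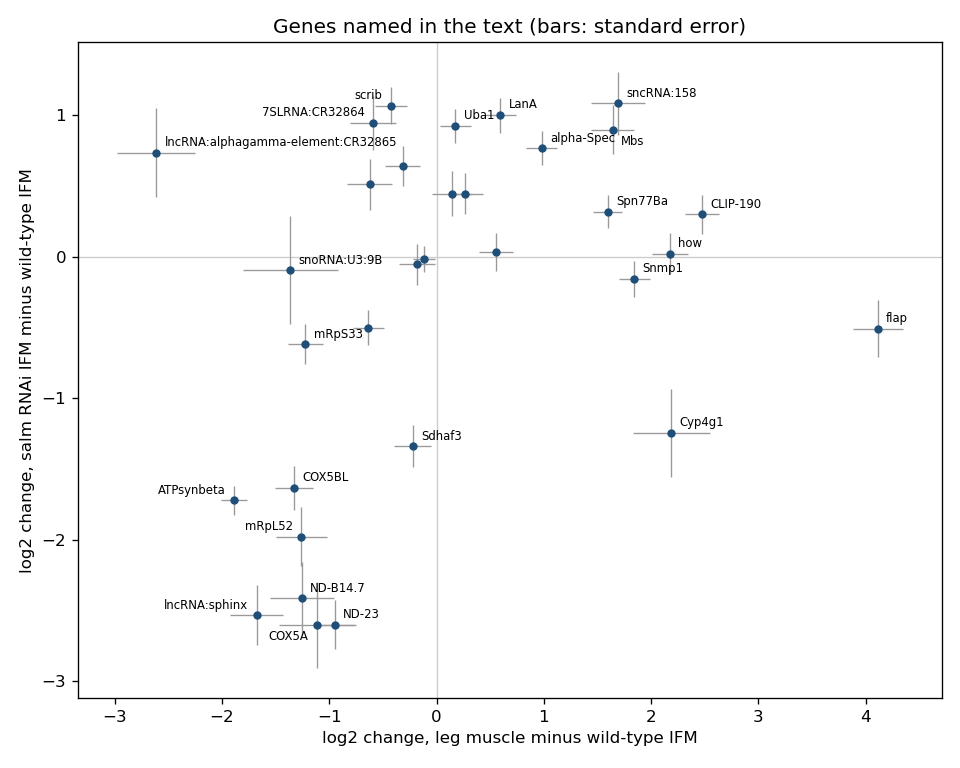
Each point is a named gene, placed by its log2 change in leg muscle (horizontal) and in salm RNAi IFM (vertical) against wild-type IFM of the same dye set, with bars of 1 standard error; points near the centre carry no name. ATPsynbeta, COX5BL, mRpL52 and ND-B14.7 lie at the lower left, while flap (4.11 and -0.51), CLIP-190 (2.47 and 0.30) and how (2.17 and 0.02) lie to the right.

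The hairpin lines were compared to see whether different RNAi constructs against salm gave like changes. ND-23 changed by -2.98 in TF3029 and -2.22 in TF10152, COX5A by -2.91 and -2.29, and ATPsynbeta by -2.27 and -1.17. ATPsynbeta was 2.14-fold lower in TF3029 than in TF10152 (-1.10, limma adjusted p = 0.00102), and ND-23 differed by -0.75 (adjusted p = 0.0344). The polarity gene scrib was higher in TF3029 (1.85) than in TF10152 (0.29), a difference of 1.57 (limma adjusted p = 0.000605). LanA differed by 0.67, mio by 0.64 and meigo by 0.60, while lncRNA:alphagamma-element:CR32865 differed by -1.98, Cyp4g1 by -1.66, Rab26 by -0.94 and brv3 by -0.82. Of the oxidative phosphorylation genes 2 of 3 were lower in TF3029 than in TF10152 (median -0.75; camera adjusted p = 0.0141, adjusted p = 0.0688 with an estimated correlation). Of the wider list of 12 mitochondrial protein genes 2 were lower (median -0.24; adjusted p = 0.294 from camera in limma). With the scan day as a block 1 of the 3 (median -0.94) and 1 of the 12 (median -0.32) were lower, so calls were lost while the medians did not shrink. On scan day 2 alone the median of the 12 was -0.25. That day held all TF3029 arrays and a single TF10152 array, on which the medians with the block rest as well.

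Against wild-type IFM, 6779 transcripts changed in TF3029 (2944 higher, 3835 lower) and 2888 in TF10152 (1268 higher, 1620 lower). Of these, 1386 were lower and 898 higher in both lines, where independent lists would share 375.5 and 225.6, and 86 went opposite ways. With the scan day as a block 1181 of 6651 TF3029 calls and 1368 of 2803 TF10152 calls held. No scan day held both TF3029 and wild-type IFM. Each array of TF3029 replicate 1 also shared its barcode with a wild-type IFM array. Both lines were set against the same wild-type samples. The correlation of their changes was 0.641, where 100 simulations of unchanged groups against those samples gave 0.499, and the covariance was 0.333 against a simulated 0.0249. With each line set against a different wild-type replicate the correlation was 0.575 and 0.629. Read with the dyes as labelled, the arrays gave 7253 changed transcripts in TF3029, 2846 in TF10152 and 3250 that differed between the lines. The lines differed for 3399 transcripts (1706 higher and 1693 lower in TF3029; limma, adjusted p under 0.05). That count was 727 with the scan day as a block, and on scan day 2, which held 3 arrays of TF3029 and 1 of TF10152, limma called 0 transcripts, with 1502 at an unadjusted p under 0.05, in a comparison of 2 samples with 1 that could hardly pass the threshold. It was 5896 without TF3029 replicate 1, and 1251 and 1206 without TF10152 replicates 1 and 2.

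Wild-type IFM was present in both dye sets, which shows how far the sets themselves differed. Of the 16547 transcripts 6241 differed between wild-type IFM replicates 1 and 2 and replicates 3 and 4 (limma, adjusted p under 0.05), and 6955 with the dyes as labelled. With the scan day or slide as a block 2355 differed. No level was therefore compared between the sets, and each change was taken within a set. The difference between the salm RNAi and leg changes does span both sets and assumes additive dye and set effects.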

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

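The counts within a single scan day were chosen only after the result was seen; the scan day slope and the correlation between the lines were planned before theirs were. Results stand here because the 2 hairpin lines, both set against the same wild-type IFM, gave changes that differed by the test of the difference itself (limma, adjusted p under 0.05).

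Transcripts of scrib, a cell polarity gene, stood 1.57 higher on the log2 scale in TF3029 than in TF10152, where the changes against wild type were 1.85 and 0.29. LanA, a laminin chain, differed by 0.67 (1.34 and 0.67). The nutrient-signalling gene mio differed by 0.64 (0.30 and -0.33), and meigo by 0.60 (0.75 and 0.15). ATPsynbeta, of ATP synthase, differed by -1.10 (-2.27 and -1.17), and ND-23, of complex I, by -0.75 (-2.98 and -2.22). Cyp4g1, an oenocyte enzyme, differed by -1.66 (-2.08 and -0.42). The noncoding RNA lncRNA:alphagamma-element:CR32865 differed by -1.98 (-0.25 and 1.73), the small GTPase gene Rab26 by -0.94 (0.17 and 1.11), and brv3, a cold-sensing channel gene, by -0.82 (-0.91 and -0.09). A search for a single sample apart from the others was run in 32 genes over the 4 wild-type IFM samples, which span both dye sets and differ between them, and its empty result says nothing of the groups of 2 samples.

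More transcripts changed in TF3029 (6779) than in TF10152 (2888), and the arrays of the lines were mostly scanned on different days. The scan day was set against this through the technical array of TF10152, scanned with TF3029. Over 3369 transcripts that differ between the lines, its departure from the first array followed the line difference with a slope of -0.01795 (bootstrap SD 0.0106). The calls that chose these transcripts include that technical array, which can pull the slope down by an amount not tested. Scan day as the whole source of the difference would give a slope near 1, far from the slope found. This argues against it as the whole source. With the scan day as a block the counts were 1185 and 1383, so TF3029 no longer had more. The block costs TF3029 precision, since no scan day held it with wild-type IFM. Of 6651 TF3029 calls 6640 kept their sign, which decides nothing. Only 86 transcripts were called opposite ways in the lines, so TF3029 changes shrunk to those of TF10152 would mostly keep their sign too. The median difference of the 3 oxidative phosphorylation genes between the lines was -0.94 against -0.75 before. It rests on the single TF10152 array scanned with TF3029, and does not decide the matter either. A stronger form of the same response in TF3029 may be the source: with each line set against a different wild-type replicate, over 7297 transcripts, the changes correlated at 0.640 and 0.682, which both a graded response and separate effects of the hairpins allow. What stays open is the scan day in part, the strength of each hairpin and effects of a hairpin on other genes. They were not told apart here. No probe could be named as salm, so the strength of each hairpin was not measured, and no test that was run separates the others. The median SD between replicates was 0.201 in TF3029, 0.072 in TF10152 and 0.078 in wild-type IFM replicates 1 and 2. A single spread per transcript was shared by all groups, so by these medians TF3029 was tested against too small a spread. How far this raised its count was not tested.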

How the results depend on the processing

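The dyes as labelled, the repeated-barcode arrays left out, the first array of TF10152 replicate 1 left out, the arrays regrouped by correlation, the Cy3 groups as 1 sample each and the counts on a single slide or scan day were chosen after seeing the data; all other alternatives here were planned. Of 64 gene results 43 passed, 40 of these kept their direction in all settings run on them, and 14 passed in all of them. The exceptions with the dyes kept as read here are the reversals below; with the dyes as labelled all directions turn. Over 1972 values of single genes, 196 lost the threshold, 50 gained it and 6 reversed. With median centring mio stood at 0.60 in leg muscle and 0.73 in salm RNAi IFM, mRpS33 at 0.20 and RpL29 at 0.83 in salm RNAi IFM and SK at 0.17 in leg muscle. Without the repeated-barcode arrays Cyp4g1 stood at 0.48 in salm RNAi IFM, where 1 wild-type and 1 TF3029 sample were left in the Cy5 set. The cause of these and of the moves below was not tested, except where fewer samples or transcripts or a stricter threshold entered. Signal over background limits dim transcripts: 9747 could be tested that were above background on all arrays, against 16547.

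Counts that moved by over 1.5 times, and correlations r of the leg and salm RNAi changes that moved, follow by setting. Without background correction 841 fell in both leg muscle and salm RNAi IFM. With processed signals 1931 were lower in leg muscle, 1939 lower in salm RNAi IFM and 561 in both, with r = 0.184. The study's table gave the same counts after its signs were turned to the dye reading used here. As submitted, its signs run the other way. With median centring 5692 were higher and 1441 lower in leg muscle, 5180 higher in salm RNAi IFM, 7131 changed in TF10152, 683 fell and 3196 rose in both, and r was 0.395. Without the filter on dim probes r was 0.270. With probes above background on all arrays 2377 were lower in leg muscle, 783 fell in both, 3865 differed between the wild-type sets and r was 0.211. Without technical arrays r was 0.184. With all arrays and the sample as a random block (consensus correlation -0.558) 3536 were higher in salm RNAi IFM, 5520 changed in TF10152, 6202 differed between the lines, 7791 between the changes, 2360 fell and 1123 rose in both, and r was 0.265. With each dye set fitted alone 2150 differed between the lines. Without a dye set term 1504 were higher and 2315 lower in leg muscle, 1850 lower in salm RNAi IFM, 4504 changed in TF3029, 1793 in TF10152, 1015 differed between the lines, 633 fell in both and r was 0.294. With scan day or slide as a block 1487 were higher and 1364 lower in leg muscle, 557 and 886 in salm RNAi IFM, 1185 changed in TF3029, 1383 in TF10152, 727 differed between the lines, 1749 between the changes, 267 fell and 131 rose in both, 2355 differed between the wild-type sets and r was 0.193; 2844 of 6298 leg calls held. With the sample channel alone 1614 were higher and 1944 lower in leg muscle, 1761 changed in TF10152, 2015 differed between the lines, 2625 between the changes, 763 fell and 323 rose in both, 4103 differed between the wild-type sets and r was 0.213.

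With a change of at least 2-fold also asked for, 1246 were higher and 1507 lower in leg muscle, 676 and 1113 in salm RNAi IFM, 3136 changed in TF3029, 1090 in TF10152, 1383 differed between the lines, 2702 between the changes, 379 fell and 159 rose in both, and 2473 differed between the wild-type sets. At an adjusted p under 0.01, 2003 were lower in leg muscle, 1335 higher and 1614 lower in salm RNAi IFM, 3986 changed in TF3029, 1365 in TF10152, 1318 differed between the lines, 2630 between the changes, 502 fell and 294 rose in both, and 3516 differed between the wild-type sets. With the dyes as labelled 4720 were higher and 2476 lower in leg muscle, 619 fell and 1652 rose in both and r was 0.268, over 18899 transcripts. Without the repeated-barcode arrays, which leaves 1 TF3029 sample, 5184 differed between the lines. With arrays regrouped by correlation 1484 were higher and 1783 lower in leg muscle, 976 and 1351 in salm RNAi IFM, 3679 changed in TF3029, 791 in TF10152, 866 differed between the lines, 1858 between the changes, 467 fell and 197 rose in both, 2745 differed between the wild-type sets and r was 0.297; 3225 of 6310 leg calls held. With each Cy3 group as 1 sample 1306 were higher and 1188 lower in leg muscle, 2150 differed between the lines, 2263 between the changes, 348 fell and 321 rose in both and 3267 differed between the wild-type sets; 2470 of 6397 leg calls held, the spread being taken from the Cy5 set. On scan day 1 alone 860 changed in TF10152. On scan day 2 alone limma called 0 between the lines, with 1502 at an unadjusted p under 0.05, from 2 samples against 1, too few to judge the calls by.

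Leaving out each sample in turn, with a lone sample assumed to vary like the other groups, gave 1751 to 2975 higher and 2280 to 5048 lower in leg muscle, 1099 to 3199 higher and 1346 to 4032 lower in salm RNAi IFM, 4164 to 7978 changed in TF3029, 1154 to 4528 in TF10152, 1206 to 5896 between the lines, 3062 to 6593 between the changes, 675 to 2063 falls and 304 to 931 rises in both, 3590 to 7862 between the wild-type sets and r of 0.205 to 0.273. Without wild-type IFM replicate 1 the counts that moved were 1273 and 1598 in salm RNAi IFM, 4187 in TF3029, 1502 in TF10152, 716 and 338 in both and 3698 between the wild-type sets. Without wild-type IFM replicate 2 they were 1099 and 1346, 4164, 1154, 675 and 304, and 3590, with 3062 between the changes. Without TF3029 replicate 1 they were 4528 in TF10152, 5896 between the lines and 2063 and 931 in both, and without TF3029 replicate 2 they were 4528 in TF10152. Without TF10152 replicate 1 they were 1356 in TF10152 and 1251 between the lines, and without its replicate 2 they were 1174 and 1206. Without wild-type IFM replicate 3 they were 2280 lower in leg muscle and 695 in both, without replicate 4 4091 between the wild-type sets, without leg replicate 1 2369 and 724, and without leg replicate 2 2287 and 730.

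With the replicate number as a block in the Cy5 set, 2457 were higher and 4081 lower in leg muscle, 2358 and 3195 in salm RNAi IFM, 6818 changed in TF3029, 3092 in TF10152, 3568 differed between the lines, 4779 between the changes, 1551 fell and 600 rose in both, 5703 differed between the wild-type sets and r was 0.243. Samples with the same number deviated together at r of 0.242, 0.149 and 0.0207, so the numbers were not taken to pair the samples, and the groups of the Cy3 set share no numbers.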

Other observations

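The tests on the dyes, on the slide and on exchanged technical arrays were chosen only after the result was seen; the test of a shared shift of the technical arrays was planned before. Beyond the genes of the comparisons, meigo rose in salm RNAi IFM (0.45, limma adjusted p = 0.0489), a call lost in 18 of the 30 settings run on it and not made in TF10152 alone (0.15), and alpha-Spec rose in leg muscle by 0.98 ± 0.14. The mitochondrial gene ND-24L fell in salm RNAi IFM (-0.86, limma adjusted p = 0.0299; not passed in TF10152 alone at -0.59) and stood at 0.52 in leg muscle, which did not pass (adjusted p = 0.183). Sdhaf3, an assembly factor of succinate dehydrogenase, changed more in salm RNAi IFM than in leg muscle, by -1.12 (limma adjusted p = 0.00858). That difference, too, holds only if dye and set effects are additive.

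In both dye sets the channel labelled as the sample was nearly alike in all groups. With the dyes as labelled the reference channel should be the more alike one. The difference in mean correlation between groups, reference minus sample, was -0.102 in the Cy5 set and -0.153 in the Cy3 set. This argues against the dyes being as labelled, but it is the pattern that set the direction and no separate support for exchanged dyes. The labels of both sets may have the dyes exchanged: a sample over a pool that contains it has a limited upper tail and an open lower tail, and with the dyes exchanged the lower tail of the log2 ratios was the longer by 2.386 in the Cy5 set and 3.53 in the Cy3 set. Those are the outer percentiles; over probes that differed by over 4-fold between groups the highest and lowest group means of red over green had medians of 1.33 and -1.37 in the Cy5 set, which shows no such asymmetry, and 0.86 and -2.02 in the Cy3 set. With the reading used here Cyp4g1 lay below the pool in all groups (-1.78 in leg muscle to -4.83 in TF3029). So did COX5BL (-0.97 in wild-type IFM replicates 1 and 2 to -3.97 in leg muscle). A pool made only of these samples would not give this, so the premise of the tail comparison is in doubt. What the pool held in each set stays open, as does whether the dyes were exchanged at all, in the labels or in the table of values. No biological explanation was tested.

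In the Cy3 set an array named as technical was less like its own sample than the other biological sample was. In leg muscle replicates 1 and 2 correlated at 0.998 and replicate 1 and its technical array at 0.903, and in wild-type IFM the values were 0.994 and 0.888; in the Cy5 set the technical arrays of wild-type IFM (0.867 with its own sample, 0.962 with replicate 2) and TF10152 (0.929 and 0.974) went the same way, and that of TF3029 did not (0.968 and 0.898). The slide was argued against, since all leg arrays lay on the same slide and the technical pair was still lower, by -0.0949. A shared shift of both technical arrays was left undecided by the correlation of their departures from the first arrays (0.449). The array named technical may hold the other biological sample, and the arrays named replicates may repeat a single sample, but the gap between the pairs (0.0949 in leg muscle and 0.106 in wild-type IFM) is the pattern itself and decides nothing; a failed or uneven labelling of the technical arrays stays open, and no biological explanation was tested.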
